A study of Mus musculus with 5 samples.

How the data were processed

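The series consists of 5 sequencing libraries from NIH3T3 cells with doxycycline-inducible CDX2: 2 CTCF immunoprecipitations with doxycycline (CTCF_Dox), 2 without (CTCF_noDox) and 1 input without. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, and CTCF was precipitated together with a spike-in of Drosophila chromatin and a Drosophila-specific H2Av antibody for normalization. Libraries were sequenced as short paired-end reads. The submitters' processing notes name STAR, Picard and MACS2, without versions or roles, and the builds mm10 and dm6. Which program aligned the reads, how duplicates were treated, what peak threshold was used, how conditions and replicates were merged and whether the spike-in entered the peak calls are not given in the sources used here.

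The deposited data used here were 1 list of peak intervals for the whole series, in which the authors had merged the peaks of both conditions. Its 3 columns give chromosome, start and end, so the unit is a position and nothing in it is normalised. There is no header, height, score, fold enrichment or q-value, and no interval carries the name of a sample. The list has 0 duplicated and 0 overlapping intervals. Depth per sample is unknown, and no test used read counts. The confidence intervals and p-values given cover only the counting of peaks or genes. A region that was not listed may have lacked reads. Coordinates are on mm10, counted from 1.

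The gene table used was NCBI RefSeq for GRCm38.p6, the assembly behind mm10, with 49997 genes. After 340 genes positioned below 3 Mb on chromosomes 1 to 19 and X were left out, because no peak lies there and those positions appear to be counted on unplaced scaffolds, and after genes off chromosomes 1 to 19, X and Y were left out, 49603 genes remained, of which 21779 were protein-coding. The table has gene starts and ends without strand, exons or sequence. The tests planned for transcription start sites therefore used both ends of each gene, within 1 kb, and the classes planned for exons, UTRs and introns became gene end, elsewhere in a gene body and outside genes, in that order. The background length planned as assembled sequence without gaps became the span from the first to the last gene or peak of a chromosome, 2660.6 Mb in all. Motif, motif orientation, repeat, base composition and score results were planned but not analysed here, since they need a genome sequence or a score. The mitochondrial peak was left out of all tests.

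The groups compared, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The comparison of doxycycline with no doxycycline was planned only for a file that ties peaks to conditions, and was not made. Chromosomes were tested with the exact two-sided binomial test against their share of the span. Peak classes and spacing were tested by permutation against 1000 random placements of the same widths on the same chromosome. Widths of gene-end and other peaks were compared by a permutation test of the difference of medians with 100000 resamples. Windows of 1 Mb were compared with the highest window of each random placement. The 20 gene lists were Hox genes, clustered protocadherins, imprinted genes, cohesin and CTCF genes, intestinal epithelium genes, trophectoderm genes, fibroblast genes, neuronal genes, blood cell genes, cell cycle and MYC genes, ribosomal protein genes, replication-dependent histone genes, olfactory receptor genes, vomeronasal receptor genes, zinc finger Zfp genes, keratin and keratin-associated genes, housekeeping genes, X inactivation genes, immediate early and AP-1 genes, and Wnt and Hippo genes. For each, the share of members with a peak within 1 kb of an end and the mean number of peaks in the body plus 10 kb each side were set against 10000 random lists of protein-coding genes from the same length deciles, two-sided. All p-values of a family were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and confidence levels were 95%.

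Named genes were chosen by this rule: from each list up to 4 members with most peaks in the body plus 10 kb; the 10 protein-coding genes with most peaks in the body; the 10 with most peaks per 100 kb among those with at least 5; up to 4 genes in each of the 3 fullest 1 Mb windows; and Cdx2, Ctcf, Rad21, H19, Igf2, Myc, Hoxa9, Hoxd13, Xist and Actb whatever their values.

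Alternatives were gene ends within 500 bp or 2.5 kb, any overlap in place of the midpoint, peaks at least as wide as the median, neighbours within 500 bp merged, protein-coding genes only or as the background of chromosomes, the gene body alone, 500 kb windows, and matching on neighbouring genes within 100 kb. Added after seeing the data were intervals from resampled 10 Mb bins, random placement within 500 kb of each peak, leaving out chromosomes X and Y, matching on length quintile and chromosome, shifting the peaks along each chromosome, random runs of neighbouring genes, which are not matched on length, and gene ends within 100 bp of each other counted once. The tests were tried on simulated placements of 22755 peaks. With no effect, the gene-end test gave p under 0.05 in 1 of 20 runs and the list test in 0 of 20. With 200 peaks planted at gene ends and a peak given to 20 of 40 list members, both did in 20 of 20. The simulated peaks were placed independently and the list members drawn at random from all protein-coding genes, with fewer placements and random lists than in the tests. These runs therefore do not measure false calls for clustered peaks or for families of neighbouring genes that share peaks. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.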

Results

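CTCF, the zinc finger protein that binds chromatin loop anchors and insulators, was mapped by chromatin immunoprecipitation and sequencing in NIH3T3 cells, a mouse embryonic fibroblast line. The cells carried a doxycycline-inducible gene for CDX2, a homeobox transcription factor of the intestine and trophectoderm. Per the labels, CTCF was precipitated in 2 libraries from cells given doxycycline for 6 h and in 2 libraries from cells without it, and 1 input library came from untreated cells, which makes 5 libraries. The labels give the dose as 500 ng/µL, a unit that could not be checked here. The values analysed here are 1 list of CTCF peak intervals in which both conditions had been merged. It held positions without heights or scores, so the number of reads behind a peak is unknown. The question the design poses, whether CDX2 induction moved CTCF binding, was not tested, because no interval was tied to a condition or replicate. Everything below describes where CTCF was called in these cells over both conditions. There was no replicate spread to compare with, and the tests set the positions of the peaks against random positions or matched genes.

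The list held 22756 peaks, of which 22755 lay on chromosomes 1 to 19, X and Y and 1 on the mitochondrial genome. Their median width was 262 bp, with quartiles of 217 and 317 bp and a range of 170 to 3800 bp. The intervals did not overlap and covered 6.51 Mb, or 0.245% of the span from the first to the last gene or peak of each chromosome.

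Per unit of length, CTCF peaks were concentrated on chromosomes 11 and 19 and were sparse on chromosomes 13, 14, 18, X and Y. Chromosome 11 carried 2527 peaks, 21.3 per Mb and 2.49 times its share by span, with a 95% range of 1.61 to 3.51 when 10 Mb bins were resampled. Chromosome 19 carried 977 peaks, 16.8 per Mb and 1.96 times its share. Chromosome 14 had 633 peaks, 5.2 per Mb and 0.608 times its share. Chromosome X had 185 peaks, 1.10 per Mb and 0.129 times its share. Its 95% range from resampled bins was 0.0628 to 0.204, wider than the exact 95% interval of 0.111 to 0.149. Chromosome Y had 16 peaks. By the exact two-sided binomial test with Benjamini-Hochberg adjustment, 8 chromosomes lay above and 9 below their share. That test treats neighbouring peaks as independent, and with intervals from resampled 10 Mb bins 2 lay above and 5 below.

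**Figure D1:**
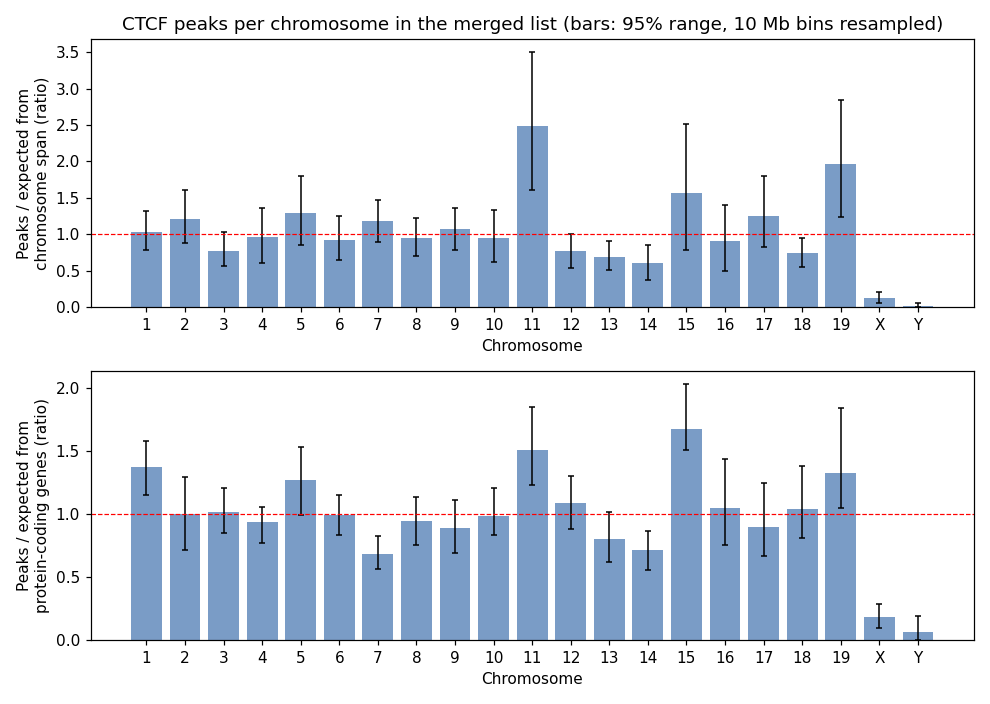
Peaks per chromosome divided by the number expected from chromosome span (top) and from the number of protein-coding genes (bottom); the bars on each column are 95% ranges from resampled 10 Mb bins and the dashed line marks a ratio of 1. Chromosome 11 stands at 2.49 by span and 1.51 by genes, and chromosome X at 0.129 and 0.184.

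Measured against protein-coding genes in place of length, chromosome 15 led with 1356 peaks, 1.68 times its share (95% range 1.51 to 2.03 from resampled bins). Chromosome 11 was at 1.51 (1.23 to 1.85), chromosome 1 at 1.38 (1.15 to 1.58) and chromosome 19 at 1.33 (1.05 to 1.84). Chromosome 7, at 1.19 by span with a range that included 1 (0.893 to 1.48), was below its share by genes at 0.682 (0.565 to 0.829). Chromosome 18, sparse by span at 0.741, was at 1.04 by genes (0.807 to 1.39), and the range of chromosome 13 by genes included 1 (0.802, 0.619 to 1.02). Chromosome 14 stood at 0.713 (0.558 to 0.866), chromosome X at 0.184 (0.0918 to 0.286) and chromosome Y at 0.0598. Within chromosome X the part from the first gene to 68 Mb held 4 peaks over 386 protein-coding genes, while 91 to 113 Mb held 66 peaks over 145 genes and 133 Mb to the end held 95 over 260. The remaining parts were sparse as well, with 18 peaks over 146 genes at 68 to 91 Mb and 2 over 26 at 113 to 133 Mb. The borders of these parts were placed after the peaks were seen. On chromosome Y, 15 of the 16 peaks lay within 110 kb between positions 90718955 and 90829051.

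**Figure D2:**
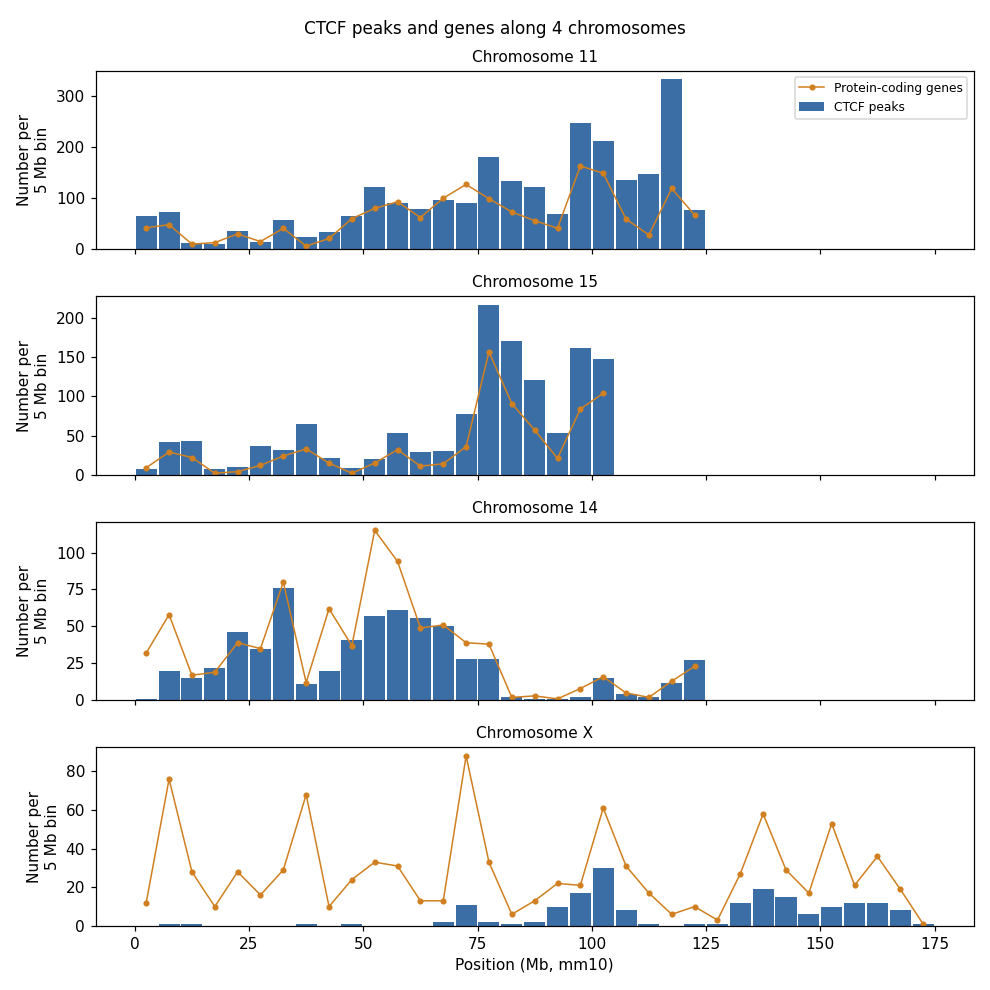
Number of CTCF peaks (columns) and of protein-coding genes (line and points) per 5 Mb along chromosomes 11, 15, 14 and X, with position in Mb on mm10. Peaks outnumber genes along most of chromosomes 11 and 15, and chromosome X holds 4 peaks before 68 Mb.

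Gene ends were enriched for CTCF peaks. Of the peaks, 3753 had their midpoint within 1 kb of either end of an annotated gene, which was 16.5% (exact 95% interval 16.0 to 17.0%) against 6.59% (6.28 to 6.92%) in 1000 random placements on the same chromosomes, a ratio of 2.50. A further 11062 peaks, 48.6% against 46.0% at random, lay elsewhere in a gene body. Outside genes lay 7940 peaks, 34.9% against 47.4% at random. Each two-sided permutation p was 0.0020, the smallest that 1000 placements can give. When each peak was placed at random within 500 kb of its own position, the gene-end ratio was 1.69, the gene-body ratio fell to 0.881, and peaks outside genes stood at 0.997 (permutation p = 0.679). The gene table gives gene starts and ends without strand or exons, so promoters, exons, introns and UTRs were not told apart.

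**Figure D3:**
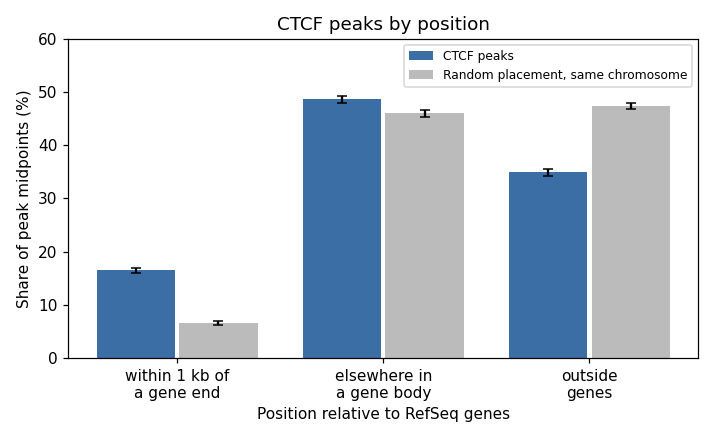
Share of CTCF peak midpoints (%) within 1 kb of a gene end, elsewhere in a gene body and outside genes, beside random placement on the same chromosome; error bars are the exact 95% binomial interval for the peaks and the 95% range of 1000 placements for the random values. The gene-end share is 16.5% against 6.59% at random.

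Peaks at gene ends were also wider. Their median width was 277 bp (quartiles 227 and 337 bp, 3753 peaks) against 259 bp (215 and 312 bp) for the 19002 others, a difference of 18 bp with a permutation p of 1e-05, the smallest that 100000 two-sided resamples can give. The median was higher at gene ends on 20 of the 20 chromosomes compared, by 1 to 29 bp.

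Peaks lay close together. The median distance between neighbouring midpoints was 32.8 kb against 69.2 kb (68.4 to 70.1 kb) for random placement, and 24.9% of neighbours were under 10 kb apart against 10.0% (permutation p = 0.0020 for both, the smallest possible). Random placement within 500 kb of each peak gave 42.4 kb and 17.2%. The end of chromosome 11 was the most crowded region: the 1 Mb from position 116000001 held 83 peaks and 35 protein-coding genes, among them Rhbdf2 with 9 peaks in its body and 10 kb each side, Mgat5b with 8, and Itgb4 and Ube2o with 7 each. The next 1 Mb held 72 peaks over 14 genes, led by Septin9, a cytoskeletal septin, with 15. The 1 Mb before them held 65 peaks over 44 genes, led by the DNA helicase gene Recql5 with 8 and the myosin gene Myo15b with 7. Of 2207 windows of 1 Mb with peaks, 32 held more than 45, the highest count in any window of 1000 random placements (permutation p = 0.0010 for the top windows, the smallest possible). Of the 10 fullest windows, 7 were on chromosome 11.

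Among 21779 protein-coding genes, 2615 (12%) had a peak within 1 kb of an end and 11065 (50.8%) had at least 1 peak in the body or within 10 kb of it. Slc39a11, a zinc transporter gene on chromosome 11 (113244851 to 113650200), held 31 peaks in its body, the highest number of any protein-coding gene. It was followed by Asic2, an acid-sensing ion channel gene on chromosome 11, with 27, and by Dnah17, an axonemal dynein gene, and Rbfox3, which encodes the neuronal splicing factor NeuN, with 18 each on the same chromosome. The calcium channel gene Cacna1a on chromosome 8 held 18, Nav2 on chromosome 7 held 16 and Sdk2 on chromosome 11 held 15. The gene models Gm37013, Gm38666 and Gm38667, which overlap one another on chromosome 18 from 36952648 to 37841873, held 17, 16 and 15. Long genes collect more peaks by chance, so density was ranked separately.

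Per 100 kb of body plus 10 kb each side, the densest gene was Tbx2, a T-box transcription factor gene on chromosome 11 (85832615 to 85841948), with 10 peaks or 34.1 per 100 kb. 1600014C10Rik on chromosome 7 had 11 peaks (32.0 per 100 kb), and Gp1bb on chromosome 16, a platelet glycoprotein gene, had 6 (27.2 per 100 kb). Rita1 on chromosome 5 had 6 peaks at 25.5 per 100 kb. Yy1, which encodes a zinc finger factor of enhancer and promoter contacts, lay on chromosome 12 (108792945 to 108820148) and had 12 peaks at 25.4 per 100 kb. Of these, 11 lay in the gene body, including 1 of 2708 bp at 108812958 to 108815665. Grasp, Bloc1s4, Thap1, Ccdc188 and Gm4981 completed the 10 densest, with 5 to 7 peaks each. Gp1bb, Rita1, Bloc1s4 and Gm4981 had no peak in the body and only flanking ones, so for short genes this ranking reflects the surroundings more than the gene.

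**Figure D4:**
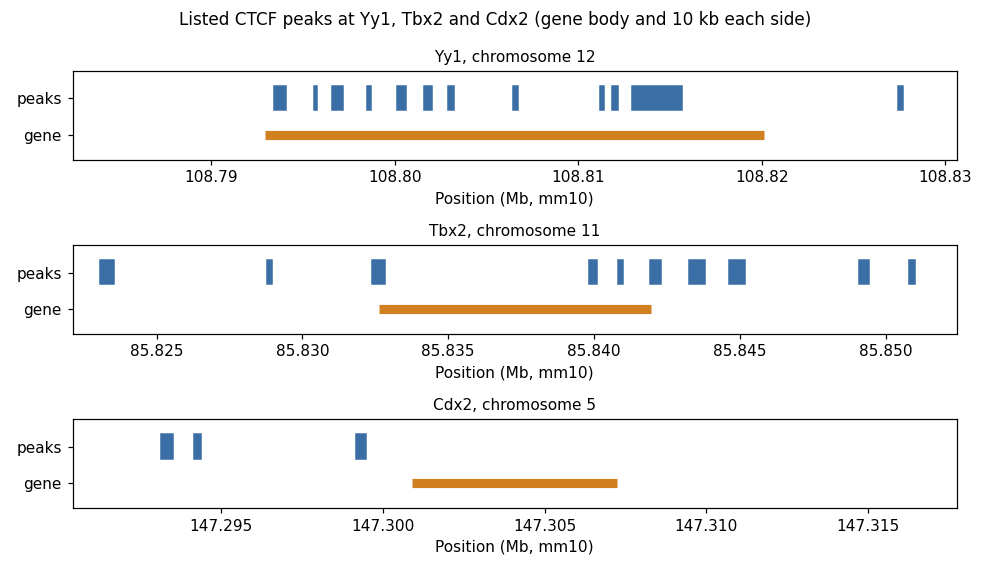
CTCF peaks (upper marks) and gene bodies (lower bars) at Yy1 on chromosome 12, Tbx2 on chromosome 11 and Cdx2 on chromosome 5, each with 10 kb on either side and position in Mb on mm10. Yy1 has 12 peaks, Tbx2 10 and Cdx2 3, all 3 of the latter on one side of the gene.

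Ribosomal protein genes carried CTCF peaks at their ends more often than genes of the same length, and so did clustered protocadherin genes, whose count rests largely on a shared end. Of 57 clustered protocadherins, which encode neuronal cell-surface proteins with alternative promoters, 34 (59.6%) had a gene-end peak against 11.8% (3.51 to 21.1%) in matched lists. A single peak of 220 bp at 37841327 to 37841546 on chromosome 18, by the common end of the gamma protocadherins such as Pcdhga1 and Pcdhgc5, counted for 21 of the genes, and matched lists hold few shared ends. With ends within 100 bp of each other counted once, an alternative added after seeing the data, 16 of 82 distinct protocadherin ends had a peak (19.5% against 6.45%, 1.22 to 12.2%; adjusted permutation p = 0.0024). Of 81 ribosomal protein genes, 32 (39.5%) did, against 12.5% (6.17 to 19.8%). Rpl38, Rpl3, Rpl12 and Rpl22 each had a gene-end peak, with 5, 5, 4 and 4 peaks in the body or within 10 kb. Each adjusted permutation p for whole genes was 0.0010 over the 20 lists, from an unadjusted p of 0.0002, the smallest that 10000 random lists can give. Ribosomal protein genes also had more peaks per gene, 1.30 against 0.632 (0.432 to 0.852), with a peak at 58 of 81 (adjusted permutation p = 0.0010). With peaks of at least median width 5 of the 57 protocadherins had a gene-end peak (8.77%, ratio 1.16, adjusted permutation p = 1), and against random runs of neighbouring genes, which are not matched on gene length, the ribosomal ratio of peaks per gene was 1.27 (adjusted permutation p = 0.281).

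Hox genes and protocadherins had more peaks per gene than length-matched genes. Among 39 Hox genes, the homeobox genes of body-axis patterning, 29 had a peak in the body or within 10 kb, at 1.33 per gene against 0.752 (0.436 to 1.10; adjusted permutation p = 0.012). These counts came from 19 distinct peaks, since neighbouring genes share them. Hoxa3, Hoxb7, Hoxb8 and Hoxb9 had 3 each, and 9 Hox genes had a gene-end peak (23.1% against 13.8%, adjusted permutation p = 0.439). Within 2.5 kb of an end 20 of the 39 did, and this passed (51.3% against 23.2%, adjusted permutation p = 0.00067), as did the gene-end test against shifted peaks (ratio 4.58, adjusted permutation p = 0.030). Protocadherins had 2.40 peaks per gene against 1.41 (0.965 to 1.96; adjusted permutation p = 0.012) from 18 distinct peaks, with 6 at Pcdha1, Pcdha2 and Pcdha3 and 5 at Pcdha4, whose bodies overlap. Neither call held against genes matched also on the number of neighbouring genes (adjusted permutation p = 0.197 for Hox genes and 0.986 for protocadherins) or against random runs of neighbouring genes without length matching (0.538 and 0.176). The Hox call was also lost in the gene body alone (ratio 1.51, adjusted permutation p = 0.588) and against genes of the same chromosome (ratio 1.52, adjusted permutation p = 0.0520). The protocadherin call was also lost with peaks of at least median width (ratio 1.55, adjusted permutation p = 0.0785) and with shifted peaks (ratio 3.56, adjusted permutation p = 0.0942), against ratios of 1.77 for Hox genes and 1.71 for protocadherins as planned; random runs gave ratios of 1.31 and 2.33 and matching on neighbours 1.34 and 1.01.

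Receptor gene families of the nose and Zfp zinc finger genes carried few peaks. Of 1109 olfactory receptor genes 1 had a gene-end peak (0.0902% against 6.11%), and of 350 vomeronasal receptor genes 1 did (0.286% against 7.30%), both with an adjusted permutation p of 0.0010. Olfactory receptor genes had 0.0595 peaks per gene against 0.351 and vomeronasal receptor genes 0.0314 against 0.532. Olfr12, Olfr1371, Olfr1396 and Olfr1410 had 2 peaks each, and so did Vmn1r2, Vmn1r3 and Vmn1r238. The neighbours Olfr12 and Olfr1410 share the same peaks, as do Vmn1r2 and Vmn1r3. One of the peaks at Vmn1r2 and Vmn1r3 was 2426 bp wide, and those at Vmn1r238 were 2365 and 2985 bp wide. They lie near the start of the assembled chromosomes 4 and 18 and are among the wide peaks near chromosome ends described under other observations, where repeated sequence may play a part. Of 367 Zfp genes 27 had a gene-end peak (7.36% against 13.7%, adjusted permutation p = 0.0016), and they had 0.545 peaks per gene against 1.06 (adjusted permutation p = 0.0010). Zfp469 had 6 peaks, Zfp536 and Zfp64 5 each and Zfp398 4. The Zfp gene-end call was lost against random runs of neighbouring genes without length matching (adjusted permutation p = 0.0720), and with all peaks shifted along their chromosomes as the background the gene-end ratio lay above 1, at 2.03 (adjusted permutation p = 0.023), while that of peaks per gene was 1.14 and did not pass (adjusted permutation p = 0.433). These families and the protocadherins consist of similar copies in which short reads can map to several places, so their counts are uncertain. Ribosomal protein genes have many pseudogene copies, which carry the same limit.

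**Figure D5:**
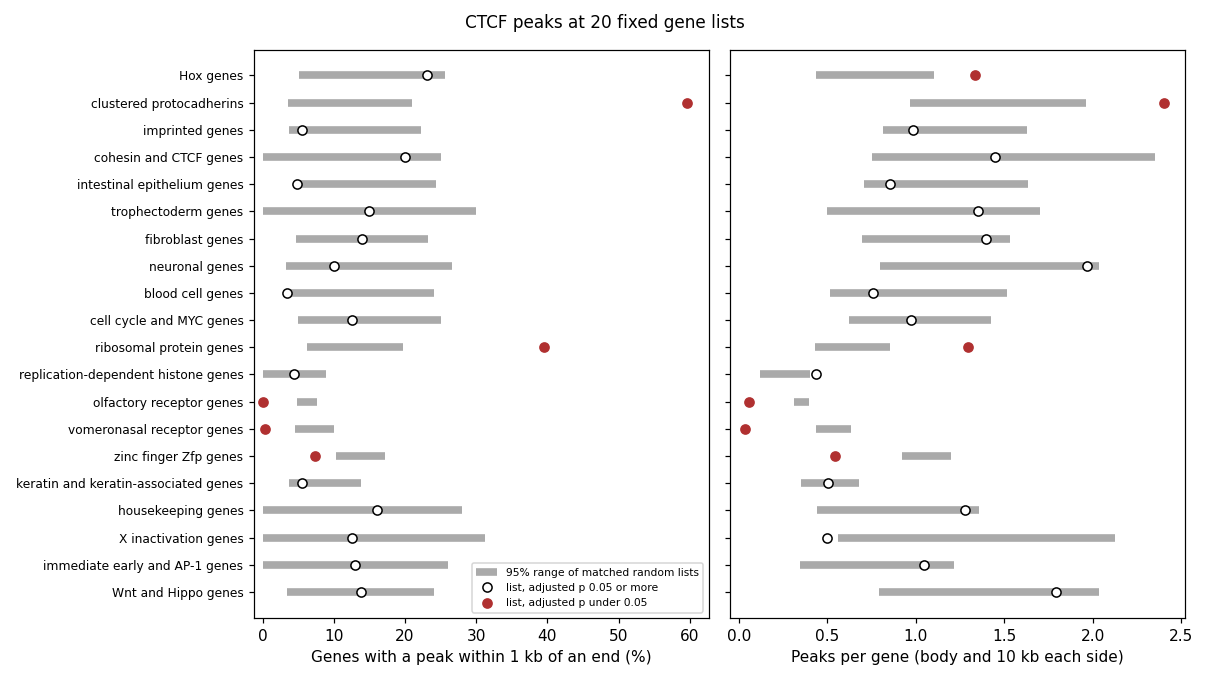
Percent of genes with a peak within 1 kb of an end (left) and peaks per gene in the body and 10 kb each side (right) for 20 gene lists; points are the lists, filled where the adjusted permutation p is under 0.05, and grey bars are the 95% range of 10000 length-matched random lists. Ribosomal protein genes (39.5%) lie to the right of their range on the left panel, as do clustered protocadherins (59.6%), where 1 peak at a shared end counts for 21 of the 34 genes.

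The lists closest to CDX2, to CTCF and to the cell type did not pass the test against matched genes. Intestinal epithelium genes had 0.854 peaks per gene against 1.12 (41 genes, adjusted permutation p = 0.364), with 6 at Ephb2, 4 at Tff3 and 3 at Gpa33. Trophectoderm genes had 1.35 against 1.03 (20 genes, adjusted permutation p = 0.421), with 4 at Elf5 and 3 at Tead4. Fibroblast genes had 1.40 against 1.07 (43 genes, adjusted permutation p = 0.300), with 6 at the collagen gene Col5a1, 4 at Pdgfra, 4 at Snai1 and 3 at Col1a1. Cohesin and CTCF genes had 1.45 against 1.43 (20 genes, adjusted permutation p = 1), of which Yy1 had 12 and Smc3 and Ctcfl 3 each. Imprinted genes had 0.981 against 1.19 (54 genes, adjusted permutation p = 0.447), with 6 at Trappc9, 5 at Commd1, 4 at Usp29 and 3 at Cdkn1c. Wnt and Hippo genes had 1.79 against 1.36 (29 genes, adjusted permutation p = 0.326), with 7 at Lrp5 and 6 at Tcf7l1. Against shifted peaks, a background of all positions and not of other genes, peaks per gene passed above for fibroblast (ratio 2.59, adjusted permutation p = 0.0067), trophectoderm (2.59, 0.013) and Wnt and Hippo genes (1.84, 0.044). Gene ends did so for fibroblast genes (ratio 4.03, adjusted permutation p = 0.020) and for cohesin and CTCF genes (6.39, 0.020).

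The remaining lists did not pass as planned either. Neuronal genes had 1.97 peaks per gene against 1.33 (30 genes, adjusted permutation p = 0.148), of which Rbfox3 alone had 19. Blood cell genes had 0.759 against 0.959, cell cycle and MYC genes 0.975 against 1.00, keratin and keratin-associated genes 0.505 against 0.508, housekeeping genes 1.28 against 0.869, and immediate early and AP-1 genes 1.04 against 0.756. Replication-dependent histone genes had 0.433 against 0.242 (67 genes, adjusted permutation p = 0.0748). That list was matched by gene symbol and takes in H1f0 on chromosome 15, so its name need not hold for every member. X inactivation genes had 0.500 against 1.24 (16 genes, adjusted permutation p = 0.0795), but against genes matched also on chromosome, and so on the sparse X, the background was 0.166, a ratio of 3.01 that did not pass (adjusted permutation p = 0.0765). With peaks of at least median width they had none against 0.643 (adjusted permutation p = 0.0032). Neuronal genes passed against random runs of neighbouring genes without length matching (ratio 1.93, adjusted permutation p = 0.040), and keratin genes lay below genes matched on chromosome for gene ends (ratio 0.322, adjusted permutation p = 0.0032) and peaks per gene (ratio 0.507, adjusted permutation p = 0.00080). Against shifted peaks, peaks per gene passed above for housekeeping (ratio 4.01, adjusted permutation p = 0.0067), immediate early (3.81, 0.0067), cell cycle (2.29, 0.011) and X inactivation genes (6.90, 0.044), and gene ends for housekeeping (4.39, 0.044), cell cycle (3.42, 0.044) and X inactivation genes (25, 0.031). As planned, none of these 14 lists passed for gene ends.

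Cdx2 itself, the gene induced from a transgene in these cells, lay on chromosome 5 at 147300900 to 147307249 with no peak in its body and 3 within 10 kb, the nearest at 147299177 to 147299467, 1.43 kb away. Ctcf on chromosome 8 had 1 peak within 10 kb, at 105685775 to 105686044, and Rad21, a cohesin subunit gene on chromosome 15, had none, its nearest peak being 50.6 kb away. No peak was listed within 10 kb of H19 or Igf2, the imprinted pair whose control region is a known CTCF site; the nearest to both lay at 142610642 to 142610854 on chromosome 7, 32.5 kb from H19 and 39.9 kb from Igf2. Myc had none within 10 kb, with its nearest at 61975082 to 61975289 on chromosome 15, 10.1 kb away. Hoxa9 and Hoxd13 had 1 flanking peak each and Actb had 1 in its body. Xist, the non-coding RNA gene of X inactivation, had 1 flanking peak at 103484161 to 103484334, which lies in the overlapping antisense gene Tsix. A gene without a listed peak can still be bound at a level below the threshold of the peak list, whose depth is unknown.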

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

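Intervals from resampled 10 Mb bins, random placement within 500 kb, leaving out chromosomes X and Y, matching on chromosome, shifted peaks, random runs of genes and shared gene ends counted once were chosen after seeing the data; the others were planned. The enrichment at gene ends, the wider peaks there, the close spacing and the 3 lists below their matched genes in peaks per gene kept their direction in each alternative run for them, except that shifted peaks put Zfp genes above; the gene-end ratio ranged from 1.69 to 3.32. Chromosomes above and below their share numbered 2 and 5 with resampled bins, in place of 8 and 9. The resampled bins take in uneven peak counts along a chromosome, from whatever source, which the binomial test does not. Against protein-coding genes the ratio passed to the other side of 1 on chromosomes 3 (1.01), 7 (0.682), 9 (0.891), 12 (1.09), 16 (1.05), 17 (0.900) and 18 (1.04), since gene density differs between chromosomes. Peaks of at least median width numbered 11385 by construction, and with them chromosome 9 stood at 0.980 and 1 list was above for gene ends, in place of 2. The gene-body ratio of 1.06 became 0.974 with gene ends within 2.5 kb and 0.881 with random placement within 500 kb, where the ratio outside genes was 0.997 and no longer passed; the cause was not tested. For peaks per gene, 1 list in place of 3 was above when matched on neighbouring genes, the ribosomal protein genes. Against random runs of neighbouring genes none of the 3 passed and 1 other did, the neuronal genes. These runs are not matched on gene length, so their background was 1.02 peaks per gene for ribosomal protein and for neuronal genes, against 0.632 and 1.33 as planned, and they do not show what neighbourhood alone changes. With peaks shifted along each chromosome, 9 lists were above for gene ends (Hox, protocadherin, cohesin and CTCF, fibroblast, cell cycle, ribosomal protein, Zfp, housekeeping and X inactivation genes) and 9 for peaks per gene (Hox, trophectoderm, fibroblast, cell cycle, ribosomal protein, housekeeping, X inactivation, immediate early, and Wnt and Hippo genes); the gene-end ratio of cell cycle and MYC genes became 3.42, of Zfp genes 2.03 and of X inactivation genes 25, and for peaks per gene 2.29, 1.14 and 6.90. The shifts set genes against all positions of a chromosome and not against other genes; beyond that the cause was not tested. Of the other values under an alternative, for single lists, chromosomes and genes, 360 kept their direction and side or, for counts, stayed within a fixed fold. A further 18 newly passed the threshold (among them Hox genes at ends within 2.5 kb, ratio 2.21) and 14 no longer did. Another 130 moved beyond the fold, which takes no account of counting error. These were peak counts of named genes, 67 with the gene body alone and 63 with peaks of at least median width. Both settings keep a part of the same peaks and so can only lower a count. Many counts were small, and the moves were not tested. No paired analysis was possible because the list ties no peak to a replicate. Leaving out replicates, other normalizations and the alternatives for motifs, orientation, repeats and base composition were not run, for want of values per sample and of sequence. Without depth, a missing peak sets no limit on binding.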

Other observations

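The tests of small RNA and other gene classes, of autosomal windows and of an even copy for chromosome X, and of wide peaks near chromosome ends were chosen after the result they measure had been seen, as were the long genes without peaks; the other tests of explanations were set before their result.

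Transfer RNA genes carried CTCF peaks near their ends more often than nearby random positions. Of 403 tRNA genes, 47 (11.7%) had a peak within 1 kb of an end against 3.24% (1.24 to 5.46%) when each peak was placed within 500 kb of its own position, a ratio of 3.60. Small nucleolar RNA genes were at 4.59% against 2.02%, long non-coding RNA genes at 8.28% against 5.12% and protein-coding genes at 12% against 6.21%; for these 4 classes the adjusted permutation p was 0.0035 over the 7 classes tested. Pseudogenes lay slightly below, at 2.10% against 2.48% (adjusted permutation p = 0.022), and microRNA and small nuclear RNA genes did not pass (adjusted permutation p = 0.105 and 0.380). Genes of the same class often lie side by side and share a peak, and tRNA and snoRNA genes often lie inside or beside other genes.

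Some of the longest genes had no peak in their body at all. Among autosomal protein-coding genes, Lrp1b, a lipoprotein receptor gene of 2058 kb on chromosome 2, and Fhit, a gene of 1612 kb on chromosome 14, led these, followed by Naaladl2, Tenm3, Lingo2 and Nkain2 with 1346 to 1208 kb. By contrast Slc39a11 held 31 peaks in 405 kb. These genes were picked because they lack peaks, and no test was run on them.

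Chromosome X before 68 Mb held 4 peaks over 386 protein-coding genes, 0.0104 per gene. A shortage of genes does not explain it: 0 of 246 autosomal windows had as few peaks per gene, the lowest being 0.644. These windows were of the same size, except for the whole of the shorter chromosome 19. They overlap heavily, so they cover far fewer separate regions than their number. Whether unplaced reads in multi-copy genes play a part was not settled. Of 47 genes there with a one-of-a-kind name 0 had a peak (exact upper limit 7.55%). The share was 60.5% of 3758 such autosomal genes and 16.0% of 94 on the rest of X. An upper limit this low had been set as the value against unplaced reads. But with only 4 peaks in this part, a low share among those 47 genes was fixed in advance. A one-of-a-kind name also does not show that reads can be placed, so this comparison cannot decide. A single even copy of the whole chromosome would give the part before 68 Mb about its share of genes, 40.1%, and it held 2.16% of X peaks (exact interval 0.592 to 5.44%). The border at 68 Mb was placed after the peaks were seen, and the exact limits given here take no account of that choice. Loss of the part of X before 68 Mb in most of these cells, a common kind of change in cultured lines, may account for its few peaks and stays a hypothesis, since copy number was not analysed here. It would not cover the sparse parts farther on, such as 68 to 91 Mb with 18 peaks over 146 genes.

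Chromosomes 11 and 15 held more peaks per gene than the autosomal trend. The mean log2 residual of 10 Mb bins from the fit on gene number was 0.57 (0.32 to 0.84) on chromosome 11 and 0.77 (0.60 to 0.95) on chromosome 15. Chromosomes 19, at 0.55 (0.19 to 0.88), and 1, at 0.38 (0.20 to 0.57), were above the trend too. By this fit the number of genes in a bin does not account for the excess, but the fit is no separate test of gene density. Chromosomes 11 and 15 had stood out by peaks per gene in the same bins, which the residual largely restates. Across the 19 autosomes the residual rose with the median width of peaks away from gene ends (Spearman's rho 0.635, permutation p = 0.0042, adjusted p = 0.0042; Pearson's r 0.766, permutation p = 0.00011, adjusted p = 0.00022). Without the 2 chromosomes farthest out in residual, 15 and 14, rho was 0.492 (permutation p = 0.046) and r 0.643 (permutation p = 0.0054). Extra DNA copies or a stronger signal on those chromosomes, which would both widen peaks and bring more of them past a threshold, could account for part of this, though not plainly for chromosome 1, where peaks away from gene ends had a median of 259 bp against 275 bp on chromosome 11, while base composition and true CTCF density remain open and untested.

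Of 59 peaks of 1 kb or wider, 17 (28.8%) lay within 1 Mb of a chromosome end against 1.94% of narrower peaks (Fisher's exact p = 1.3e-15). Without chromosome Y 20.8% of 53 did, and no test was run for these. Fisher's test treats neighbouring peaks as independent, yet 6 of the 17 lay within 110 kb on chromosome Y. The p-value therefore overstates the evidence. The widest were 3800 bp on chromosome 14 at 19415849, 3769 bp on chromosome 4 at 3081255 and 3360 bp on chromosome 11 at 3100530. Repeated sequence near the ends of the assembled chromosomes, where reads of many copies pile up, may account for part of these, and no biological explanation was tested. Whether neighbouring peaks were joined across gaps of 100 bp or more stays open. In the list 9 gaps under 100 bp remain, which had been set as the value against it. They are, however, 2.36% of the 382 gaps under 500 bp (exact interval 1.08 to 4.43%), against 20% if even. Gaps of 100 to 200 bp were few too, 36 against 130 at 200 to 300 bp and 104 at 300 to 400 bp. The shortage thus did not stop at 100 bp. A merge of several calls could leave a few small gaps after joining within each. The other 42 wide peaks, among them the widest of all and that of 2708 bp at Yy1, lie farther from an end and stay unexplained.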
